A study of Rhododendron with 15 samples.

How the data were processed

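Leaf polyA RNA of Rhododendron 'xiaotaohong' was sequenced by the authors in 15 libraries, 3 for each of 5 groups: 25 °C, 35 °C and 40 °C without melatonin, and 35 °C and 40 °C with melatonin. Per the labels, RNA was extracted with Trizol and selected with oligo(dT), and libraries were built by a stranded dUTP protocol. The strand used for counting is not given in the sources used here. The labels do not say whether the replicates come from separate plants.

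Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d were used, with no role or order given. Per the file headers, the deposited table holds a count and an FPKM value (fragments per kilobase and 1e6 fragments) for each of 29985 genes in each library. The count values deposited by the authors are whole numbers without normalization. Among counts of 1 to 20, 58.8 to 63.0% were even, as where both mates of a fragment are counted, so count totals may exceed the number of fragments. The FPKM values deposited by the authors were checked against the counts: for all 7006 genes with more than 1000 counts, the ratio of the pair was explained within 1% by 1 factor per library and 1 per gene. The column names begin with CK or MT, and CK was read as without and MT as with melatonin, from the series design. Another 6 per-sample value columns, whose names carry MT and 25, match no sample in the labels and were not used. By the same reading they would be 25 °C with melatonin, which the labels do not state.

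Genes carry identifiers of an annotation and of assembled loci, and coordinates are those of the table. The genome build is not given in the sources used here. A description was present for 23230 genes, an informative one for 20077. Loci with several gene names (1316 genes) are called merged, since their counts sum over genes. Genes without a gene name (3033) held 5.05 to 6.05% of the counts. Close paralogs were not separated further.

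The comparisons, tests, gene lists and alternatives were chosen before the data were examined. The plan named limma on log2(FPKM + 1) as the main test unless the table held counts. It did, so edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) became the main test and limma (3.58.1) an alternative. The edgeR fit used TMM scaling, filterByExpr, 5 group means and 10 residual degrees of freedom, without covariates, on 26183 genes. Each p-value is two-sided and adjusted by Benjamini-Hochberg over genes within a comparison, and genes were called at adjusted p under 0.05. The comparisons were 35 °C and 40 °C with 25 °C, 40 °C with 35 °C, melatonin with none at 35 °C and at 40 °C, and the difference between those melatonin effects. Library totals were between 54300447 and 68267949 counts. In simulated data with the depths of all 15 libraries and the fitted spread, changes at 40 °C were planted only in genes well counted at 25 °C. Of these, 71 of 100 with a log2 change of 1 and 97 of 100 with a log2 change of 2 were recovered. There were 5 false calls among the 26183 genes simulated. Few genes changed in the simulation, so it does not test the scaling where most genes move.

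Gene lists were 45 sets of genes matched by words in their descriptions, of which 44 had at least 5 tested members. They were tested with camera in limma at a preset correlation of 0.01, which asks whether a list's genes rank higher or lower than the other genes, and adjusted over lists. Stray members were left in. Beside it, the correlation was estimated per list, and the fry test was run, which asks whether a list's genes move on balance one way without comparing them with other genes. Members were counted as called over all genes and also when adjusted over the list alone.

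Genes named in the report follow a rule set in advance. For each pairwise comparison it takes the 6 largest rises and 6 largest falls in log2(FPKM + 1) among called genes with an informative description, a mean FPKM of at least 5 in the higher group and all 3 libraries of one group above those of the other. It adds, for up to 6 called lists, the 2 members with the smallest adjusted p in the list's direction and 1 in the other, and up to 3 called genes each of the heat stress transcription factor and melatonin biosynthesis lists. For the difference of melatonin effects it takes the 6 smallest adjusted p. The text draws on this set and shows levels of these genes in other comparisons as well.

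The covariance of heat and melatonin log2 fold changes, here differences in mean log2 CPM, was compared with 1000 simulated draws without effects. This was done because the untreated heat libraries enter both. It was repeated with different libraries of that group in each fold change. Alternatives were median-of-ratios scaling (RLE), no count filter, DESeq2 1.42.0 (genes without an adjusted p left so), limma on FPKM with other pseudocounts, filters, scalings and variance settings, fits on the compared groups alone, a replicate block, stricter thresholds, and leaving out each library in turn. KEGG pathways in the table's annotation with at least 10 genes (122 pathways) were tested after the data were seen.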

Results

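Transcript levels were measured by polyA RNA sequencing in leaves of the Rhododendron variety 'xiaotaohong', a woody ornamental plant. Leaves came from plants at 25 °C, at 35 °C and at 40 °C without melatonin, and at 35 °C and 40 °C with melatonin, an indole compound made from tryptophan in plants as well as animals. Each of these 5 groups held 3 libraries. The series title names tolerance of high temperature and its improvement by melatonin as the subject. The melatonin dose, the length of the heat exposure and the hour of harvest are not given in the sources used here. Total counts per library were 56619232 to 57576522 at 25 °C, 64813626 to 68267949 at 35 °C, 59362192 to 65795707 at 40 °C, 58101685 to 61664742 at 35 °C with melatonin and 54300447 to 61137577 at 40 °C with melatonin. Of the 29985 genes listed, 26183 passed the count filter and were tested. The labels do not say whether the replicates come from separate plants, so every p-value measures the spread between these samples, which may be technical.

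Libraries of 1 group resembled each other closely, and the groups differed with temperature and with melatonin, more so at 40 °C than at 35 °C. Across genes, the correlation of log2 CPM between libraries of the same group was 0.968 to 0.974. It was 0.724 to 0.729 between the 25 °C and 40 °C libraries, and 0.831 to 0.835 between the 25 °C libraries and those at 40 °C with melatonin. At 40 °C, libraries with and without melatonin correlated at 0.885 to 0.891, below the 0.927 to 0.936 between 25 °C and 35 °C and the 0.896 to 0.899 between 35 °C and 40 °C with melatonin. At 35 °C, those with and without melatonin correlated at 0.952 to 0.960, below the values within groups. The first principal component held 58.9% of the variance and ordered the groups from 25 °C through both 35 °C groups and 40 °C with melatonin to 40 °C. Genes are not independent replicates, so these correlations describe the libraries only.

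**Figure D1:**
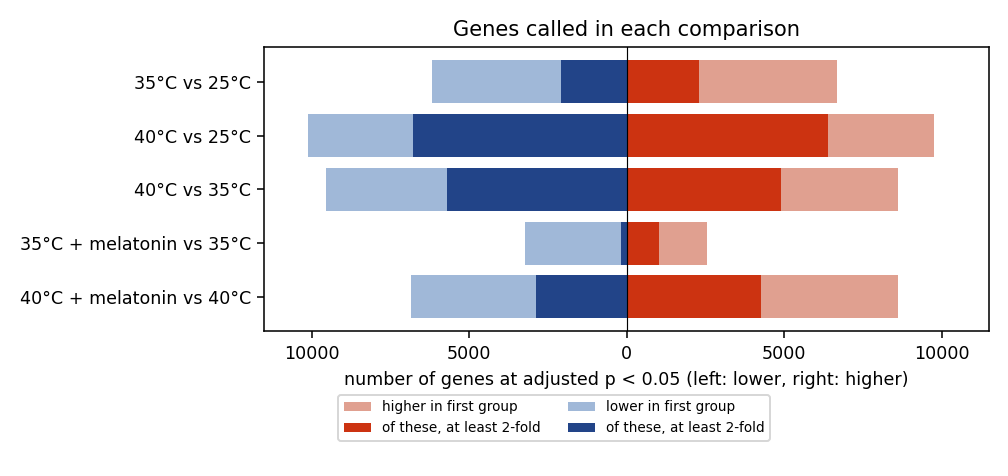
Number of genes with a difference between groups in each of the 5 pairwise comparisons (horizontal axis, genes at adjusted p under 0.05, lower to the left and higher to the right of 0), with the darker part of each bar standing for changes of at least 2-fold. The bars are longest for 40 °C against 25 °C, with 9754 genes higher and 10107 lower, and shortest for melatonin at 35 °C, with 2540 higher and 3223 lower.

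The comparison of 35 °C with 25 °C asked what moderate heat did without melatonin. Small heat shock proteins, which bind unfolding proteins, showed some of the largest rises, while more HSP70 genes, which encode ATP-driven chaperones, fell than rose, and most proteasome subunits fell. An Hsp20-domain gene (MSTRG.22177, chromosome 13, 8463100 to 8463576) rose from 3.82 ± 0.950 to 224 ± 3.73 FPKM (mean ± SD, n = 3 per group), a log2 fold change of 5.81 ± 0.11 (SE) with an adjusted p of 1.6e-14. A second small heat shock protein gene (MSTRG.5787, chromosome 3, 33708761 to 33710658) rose from 0.749 ± 0.200 to 58.2 ± 7.68 FPKM, by 6.20 ± 0.14 on the log2 scale. Of the 32 small heat shock protein genes tested, 15 rose and 7 fell, the median log2 fold change was 0.82, and 22 passed when adjusted over the list alone. One that fell was a class I gene (MSTRG.22059), from 249 ± 10.3 to 63.8 ± 1.45 FPKM. Against the other genes, the list was higher in the camera test with its preset correlation (adjusted p = 0.022), but not with one estimated from the data (adjusted p = 0.13 with an estimated correlation). Members of this family can be near-identical, so the split of reads between them is uncertain.

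Among 34 HSP70 family genes at 35 °C, 18 fell and 8 rose, 27 passed when adjusted over the list alone, and the median log2 fold change was -0.64 (adjusted p = 0.043; adjusted p = 0.26 with an estimated correlation). The list includes 1 heat shock cognate gene of the HSP90 type. The members with the smallest adjusted p among those that fell were MSTRG.7480, from 1814 ± 7.57 to 441 ± 11.2 FPKM, and MSTRG.22180, from 991 ± 14.7 to 192 ± 4.23 FPKM. A chloroplast stromal member (MSTRG.18891) rose instead, from 2.55 ± 0.197 to 35.9 ± 0.757 FPKM. Proteasome subunits, which form the complex that degrades ubiquitin-tagged proteins, fell in 34 of 49 cases and rose in 3, with 38 passing when adjusted over the list alone. Their median log2 fold change was -0.36 (adjusted p = 2.9e-05; adjusted p = 0.10 with an estimated correlation), and an alpha subunit (MSTRG.10230) fell from 58.5 ± 2.01 to 37.0 ± 1.10 FPKM. One of the 3 that rose, MSTRG.3658, is a merged locus described as an esterase.

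Other large changes at 35 °C lay outside the chaperones. Rubisco activase 1 (MSTRG.9620, chromosome 5, 31570269 to 31573635), which frees the active sites of the carbon-fixing enzyme Rubisco, rose from 9.67 ± 0.523 to 171 ± 4.33 FPKM (log2 fold change 4.08 ± 0.04, adjusted p = 4.6e-17). A gene described as a stem-specific protein (MSTRG.3246) rose from 70.8 ± 2.87 to 1075 ± 68.2 FPKM. A pair of metalloendoproteinase genes on chromosome 8 fell to near 0, MSTRG.14064 from 89.7 ± 6.53 to 0.171 ± 0.0976 FPKM and MSTRG.14046 from 114 ± 3.49 to 0.508 ± 0.256 FPKM. A boron transporter-like gene (MSTRG.21608) fell from 22.1 ± 1.62 to 0.215 ± 0.0812 FPKM. Of 19 heat stress transcription factors, 4 rose and 6 fell, and the list as a whole did not pass (adjusted p = 0.69). The A-6b-like factor (MSTRG.2066) fell from 34.5 ± 6.67 to 3.29 ± 0.547 FPKM, HSF30 (MSTRG.18818) from 15.9 ± 2.35 to 3.55 ± 0.567 FPKM, and MSTRG.14339 from 10.6 ± 0.530 to 6.17 ± 0.608 FPKM.

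By edgeR's quasi-likelihood test, 12846 of the 26183 genes differed between 35 °C and 25 °C, 6674 higher and 6172 lower, of which 2283 and 2090 changed at least 2-fold. With median-of-ratios scaling in the same test, 6219 were higher and 6598 lower. On FPKM rescaled by median ratios, the limma fit put 851 genes at least 2-fold higher and 1478 lower.

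At 40 °C against 25 °C, the same question was asked of severe heat, and transcripts of photosynthesis, the Calvin cycle, wax and fatty acid enzymes, flavonoid enzymes and the auxin and jasmonate pathways fell while small heat shock proteins rose. MSTRG.5787 went from 0.749 ± 0.200 to 1928 ± 43.0 FPKM, a log2 fold change of 11.40 ± 0.16, and MSTRG.22177 from 3.82 ± 0.950 to 4317 ± 79.7 FPKM, a log2 fold change of 10.22 ± 0.12 (adjusted p = 8.7e-17 and 2.4e-17). Of the 32 small heat shock protein genes, 22 rose, 20 of them at least 2-fold, and 8 fell, with 30 passing when adjusted over the list alone. The median log2 fold change was 2.69 (adjusted p = 0.0026; adjusted p = 0.056 with an estimated correlation). MSTRG.22059 again fell, to 26.5 ± 2.46 FPKM. DnaJ co-chaperones, the partners of HSP70, rose in 36 of 60 cases and fell in 11, with 47 passing when adjusted over the list alone (median 0.41, adjusted p = 0.018; adjusted p = 0.065 with an estimated correlation).

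Photosynthesis genes fell together at 40 °C. Of 17 light-harvesting proteins 14 fell and 1 rose, with 15 passing when adjusted over the list alone (median log2 fold change -1.74, adjusted p = 0.00053; adjusted p = 0.059 with an estimated correlation). The most abundant among those named (MSTRG.6506, chromosome 4, 3362537 to 3364019), which binds chlorophyll a and b in the antenna, fell from 3034 ± 30.7 to 361 ± 8.34 FPKM, and MSTRG.24636 fell from 686 ± 22.0 to 3.24 ± 0.377 FPKM. Of 43 genes for photosystems and electron transport 35 fell and 5 rose, with 41 passing when adjusted over the list alone (median -1.17, adjusted p = 9.8e-06; adjusted p = 0.067 with an estimated correlation). Among them, photosystem I subunit V (MSTRG.6307) fell from 1794 ± 36 to 156 ± 11.1 FPKM. An oxygen-evolving enhancer-like gene (MSTRG.13082) rose by 1.09 on the log2 scale, to 28.0 ± 0.705 FPKM. In the Calvin cycle list, 10 of 11 genes fell, all 11 passed when adjusted over the list alone, and the median was -1.56 (adjusted p = 0.0098; adjusted p = 0.11 with an estimated correlation). Rubisco activase 2 (MSTRG.22136, chromosome 13, 7741349 to 7745360) fell from 5143 ± 20.8 to 588 ± 10.3 FPKM, a log2 fold change of -3.04 ± 0.02, and phosphoribulokinase (MSTRG.12778) from 587 ± 12.3 to 99.8 ± 2.18 FPKM. Rubisco activase 1 (MSTRG.9620) was the only member that rose, to 154 ± 4.75 FPKM.

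Wax and fatty acid enzymes fell in 40 of 61 cases and rose in 13, with 53 passing when adjusted over the list alone (median -1.92, adjusted p = 0.0098; adjusted p = 0.056 with an estimated correlation). A 3-ketoacyl-CoA synthase (MSTRG.14211), which starts the elongation of very long fatty acids for cuticular wax, fell from 320 ± 10.8 to 5.41 ± 0.406 FPKM, while a fatty acid desaturase (MSTRG.7077) rose from 4.33 ± 0.461 to 209 ± 1.36 FPKM. Flavonoid and anthocyanin enzymes fell in 37 of 69 cases and rose in 14, with 50 passing when adjusted over the list alone (median -1.19, adjusted p = 0.013; adjusted p = 0.059 with an estimated correlation). Genes of auxin signalling fell in 54 of 92 cases, with 78 passing when adjusted over the list alone, and bHLH transcription factors in 45 of 73, with 61 passing. These lists had medians of -1.17 and -1.01 and adjusted p of 0.011 and 0.011, and they alone of the 11 called lists also held with an estimated correlation (adjusted p = 0.047 for both). Jasmonate genes fell in 21 of 30 cases and rose in 7, with 28 passing when adjusted over the list alone (median -1.40, adjusted p = 0.0098; adjusted p = 0.056 with an estimated correlation). A lipoxygenase (MSTRG.7855), an enzyme that oxidises polyunsaturated fatty acids, fell from 50.9 ± 2.30 to 1.55 ± 0.144 FPKM, while an allene oxide synthase (MSTRG.13459) rose from 1.27 ± 0.292 to 17.0 ± 1.07 FPKM. Ribosomal proteins rose in 115 of 226 cases and fell in 64, with 179 passing when adjusted over the list alone (median 0.33, adjusted p = 0.040; adjusted p = 0.45 with an estimated correlation).

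Single genes changed over wider ranges at 40 °C. A xyloglucan endotransglucosylase/hydrolase (MSTRG.22297, chromosome 13, 10628236 to 10631847), an enzyme that remodels cell wall xyloglucan, rose from 0.572 ± 0.157 to 599 ± 13.4 FPKM, and a beta-D-xylosidase (MSTRG.8066) from 3.77 ± 0.206 to 1658 ± 103 FPKM. A germin-like gene (MSTRG.23584) had 0 counts in all 25 °C libraries and 299 ± 26.4 FPKM at 40 °C. Granule-bound starch synthase (MSTRG.5792, chromosome 3, 33743555 to 33747716), which makes amylose, fell from 932 ± 23.3 to 3.95 ± 0.278 FPKM. A peroxidase (MSTRG.13552) fell from 1421 ± 33.2 to 0.345 ± 0.123 FPKM and a sulfate transporter-like gene (MSTRG.21782) from 182 ± 4.97 to 0.134 ± 0.127 FPKM. Among 19 heat stress transcription factors 9 rose and 7 fell (adjusted p = 0.59 for the list), with HSF B3 (MSTRG.4397) rising from 15.1 ± 1.40 to 121 ± 1.47 FPKM and MSTRG.2066 falling to 1.25 ± 0.407 FPKM.

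By the same test, 19861 genes differed between 40 °C and 25 °C, 9754 higher and 10107 lower, of which 6397 and 6776 changed at least 2-fold. The share of counts from the mitochondrial genome moved with the heat at 40 °C, from 0.0239% ± 0.0031 at 25 °C to 0.214% ± 0.011. Markers of vascular tissue fell in 29 of 55 cases and rose in 10, although the list as a whole did not pass (adjusted p = 0.074).

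**Figure D2:**
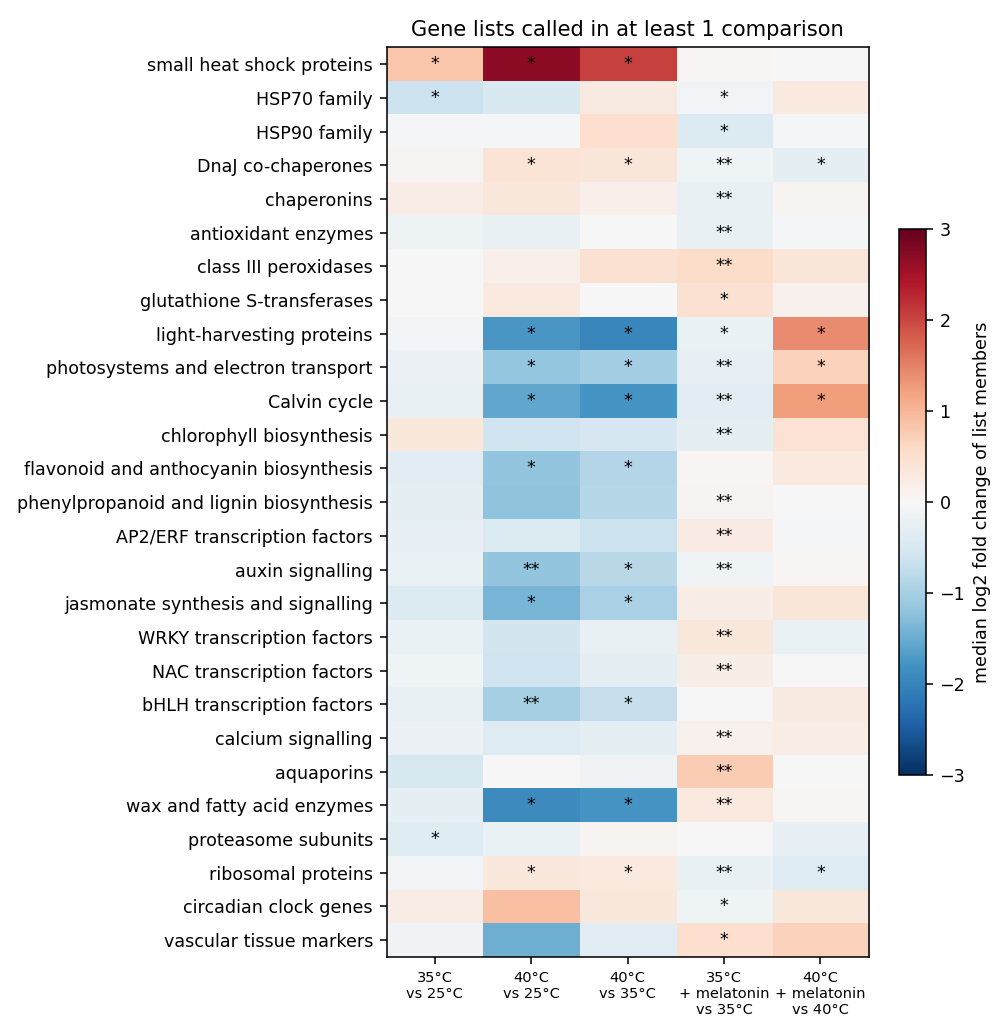
Median log2 fold change (colour, -3 to 3) of the 27 gene lists called in at least 1 of the 5 pairwise comparisons (columns), each row being 1 list. A single star marks a call by the camera test with the preset correlation and a double star a call that also held with an estimated one. The medians at 40 °C against 25 °C run from -1.92 for wax and fatty acid enzymes to 2.69 for small heat shock proteins.

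Setting 40 °C against 35 °C separates severe from moderate heat, and in this step photosynthesis transcripts fell and small heat shock proteins rose. Light-harvesting proteins fell in 13 of 17 cases (median log2 fold change -1.95), photosystem and electron transport genes in 33 of 43 (median -1.01) and Calvin cycle genes in 9 of 11 (median -1.78), with adjusted p of 0.0011, 1.6e-05 and 0.0013. Adjusted over the list alone, 15, 40 and 10 members passed, and none of these lists held with an estimated correlation (adjusted p = 0.073 for each). MSTRG.6506 fell from 3879 ± 70.6 to 361 ± 8.34 FPKM, with an adjusted p of 3.9e-19, and Rubisco activase 2 (MSTRG.22136) from 4633 ± 15.7 to 588 ± 10.3 FPKM, with an adjusted p of 1.1e-19. Small heat shock proteins were higher at 40 °C than at 35 °C in 23 of 32 cases and lower in 6, with 29 passing when adjusted over the list alone (median 2.05, adjusted p = 0.00036; adjusted p = 0.051 with an estimated correlation). HSF30 (MSTRG.18818), lower at 35 °C than at 25 °C, rose from 3.55 ± 0.567 to 41.7 ± 3.39 FPKM, and HSF B3 (MSTRG.4397) from 17.2 ± 1.19 to 121 ± 1.47 FPKM. A C-1-like factor (MSTRG.836) fell from 27.4 ± 1.83 to 11.4 ± 0.586 FPKM.

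Genes with the steepest falls from 35 °C to 40 °C included a sieve element occlusion B-like gene (MSTRG.14865, chromosome 8, 26951012 to 26956715), whose family makes phloem filament proteins, from 370 ± 3.4 to 0.551 ± 0.253 FPKM. An aquaporin (MSTRG.8662) fell from 371 ± 8.24 to 0.644 ± 0.0690 FPKM and a carbonic anhydrase (MSTRG.14796), which interconverts carbon dioxide and bicarbonate, from 180 ± 10.9 to 0.781 ± 0.236 FPKM. A NIP-type aquaporin-like gene (MSTRG.17531), of another branch of the water channel family, went the other way, from 0.0391 ± 0.0677 to 85.2 ± 6.11 FPKM. Ribosomal protein transcripts rose in 114 of 226 cases and fell in 41, with 155 passing when adjusted over the list alone (median 0.29, adjusted p = 0.0026; adjusted p = 0.25 with an estimated correlation). S6 (MSTRG.10579) rose from 184 ± 0.689 to 426 ± 14.7 FPKM. Wax and fatty acid enzymes (39 of 61 lower), auxin signalling (54 of 92), jasmonate (21 of 30), flavonoid (36 of 69) and bHLH genes (36 of 73) fell here too, and DnaJ co-chaperones (31 of 60 higher) rose. Their adjusted p were 0.022, 0.0083, 0.0052, 0.028, 0.028 and 0.022 in that order. None of these 6 lists held otherwise (adjusted p = 0.073, 0.051, 0.053, 0.073, 0.058 and 0.073 with an estimated correlation). In all, 18154 genes differed, 8597 higher and 9557 lower, and 4887 and 5715 of them changed at least 2-fold. The median log2 fold change of all genes was -0.07 here and -0.18 on the FPKM scale as deposited, where limma called 7156 higher and 10157 lower. On rescaled FPKM the balance of changes of at least 2-fold turned round, with 3889 higher and 3429 lower.

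The comparison of 35 °C with and without melatonin asked what melatonin did under moderate heat. Ribosomal protein, chlorophyll biosynthesis, photosystem and Calvin cycle genes fell slightly, and WRKY transcription factors, class III peroxidases, aquaporins and wax enzymes rose. Ribosomal proteins fell in 100 of 226 cases and rose in 5, with 110 passing when adjusted over the list alone (median log2 fold change -0.23, adjusted p = 6.9e-12), and S6 (MSTRG.10579) went from 184 ± 0.689 to 128 ± 3.34 FPKM. Chlorophyll biosynthesis genes fell in 15 of 25 cases and rose in 0, with 18 passing when adjusted over the list alone (median -0.29, adjusted p = 5.0e-08). The H subunit of magnesium chelatase (MSTRG.7116), the enzyme that puts magnesium into the chlorophyll precursor, fell from 254 ± 3.93 to 173 ± 5.12 FPKM, a log2 fold change of -0.66 ± 0.03. Photosystem and electron transport genes fell in 20 of 43 cases and rose in 1, and Calvin cycle genes fell in 7 of 11 (medians -0.25 and -0.31, adjusted p = 7.0e-06 and 0.00033), with 23 and 7 passing when adjusted over the list alone. Rubisco activase 2 (MSTRG.22136) fell from 4633 ± 15.7 to 3584 ± 9.07 FPKM and sedoheptulose-1,7-bisphosphatase (MSTRG.16649) from 420 ± 8.04 to 296 ± 7.02 FPKM. Chaperonins fell in 12 of 31 cases (median -0.22, adjusted p = 0.00015), among them both named subunits of the complex that helps assemble Rubisco, MSTRG.1639 and MSTRG.21490, by 0.49 and 0.42 on the log2 scale.

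WRKY transcription factors, plant regulators of stress and defence genes, rose in 23 of 59 cases and fell in 5, with 30 passing when adjusted over the list alone (median 0.35, adjusted p = 9.2e-06). WRKY31-like MSTRG.22647 rose from 2.55 ± 0.196 to 12.3 ± 0.781 FPKM and MSTRG.10412 from 54.5 ± 4.92 to 143 ± 2.69 FPKM. Class III peroxidases, which oxidise phenolics in the cell wall, rose in 10 of 38 cases and fell in 2, and aquaporins in 8 of 23 and 2, with 13 and 12 passing when adjusted over the list alone (medians 0.55 and 0.76, adjusted p = 0.00071 and 0.0011). The aquaporin list includes a TIP41-like gene, which is no water channel. Phenylpropanoid and lignin genes rose in 16 of 49 cases, wax and fatty acid enzymes in 22 of 61, AP2/ERF factors in 19 of 91, NAC factors in 9 of 42 and calcium signalling genes in 20 of 108, with adjusted p of 0.0023, 0.0031, 0.0062, 0.0075 and 0.049. Lists that fell were DnaJ co-chaperones (18 of 60), antioxidant enzymes (13 of 28) and auxin signalling (26 of 92), with adjusted p of 0.0035, 0.0049 and 0.031. All lists named so far for this comparison also held with an estimated correlation, 16 of the 22 called. The other 6 did not. Of these, HSP90 (4 of 6 lower), light-harvesting proteins (8 of 17 lower), HSP70 (11 of 34 lower) and circadian clock genes (4 of 12 lower) fell, and vascular markers (16 of 55 higher) and glutathione S-transferases (12 of 45 higher) rose. Their adjusted p with an estimated correlation were 0.053, 0.096, 0.25, 0.091, 0.15 and 0.11, against adjusted p of 0.00046, 0.0093, 0.030, 0.049, 0.022 and 0.024 with the preset one. The HSP70 median was -0.09 and its mean 0.05, so they differ in sign.

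Among the largest rises with melatonin at 35 °C was that of ferredoxin-nitrite reductase (MSTRG.19778, chromosome 11, 30009532 to 30013043), the plastid enzyme that turns nitrite into ammonium, from 11.3 ± 1.0 to 115 ± 1.19 FPKM (log2 fold change 3.24 ± 0.09, adjusted p = 1.8e-11). A phylloplanin-like gene (MSTRG.2278), whose family is secreted onto the leaf surface, rose from 1.10 ± 0.166 to 52.6 ± 4.26 FPKM and an isoflavone reductase-like gene (MSTRG.10231) from 1.42 ± 0.263 to 31.8 ± 0.808 FPKM. An ethylene-responsive factor (MSTRG.11070) rose from 0.907 ± 0.137 to 20.4 ± 0.350 FPKM, a daurichromenic acid synthase (MSTRG.16335) from 0.501 ± 0.198 to 10.5 ± 1.0 FPKM, and a peroxidase (MSTRG.5298) went from 0.0434 ± 0.0752 to 11.2 ± 1.15 FPKM. The sieve element occlusion B-like gene MSTRG.14865 fell from 370 ± 3.4 to 60.5 ± 0.489 FPKM. Among the heat stress transcription factors, HSF B3 (MSTRG.4397) rose from 17.2 ± 1.19 to 58.2 ± 3.79 FPKM and MSTRG.14339 from 6.17 ± 0.608 to 15.9 ± 0.546 FPKM, and a B-2a-like factor (MSTRG.5488) fell from 39.6 ± 5.16 to 21.0 ± 1.75 FPKM.

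Melatonin at 35 °C changed 5763 genes, 2540 higher and 3223 lower, but of the changes of at least 2-fold 1028 were rises and 176 falls. The direction of small changes moved with the scaling: limma on the FPKM values as deposited called 6444 genes, 4330 higher and 2114 lower, and on rescaled FPKM 2983 higher and 3337 lower.

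At 40 °C, the comparison with and without melatonin asked the same under severe heat, and light-harvesting, photosystem and Calvin cycle transcripts were higher with melatonin and ribosomal protein transcripts were lower. Transcripts of the plastid genome that passed the oligo(dT) selection did not share this rise, with 1 of 19 higher, 2 lower and a median log2 fold change of -0.02. Plastid RNA without a polyA tail was not measured, so whether plastid transcript levels as a whole rose is not known. Light-harvesting proteins rose in 13 of 17 cases and fell in 2, with 15 passing when adjusted over the list alone (median log2 fold change 1.41, adjusted p = 0.00034; adjusted p = 0.17 with an estimated correlation). MSTRG.6506 went from 361 ± 8.34 to 2265 ± 8.44 FPKM, a log2 fold change of 2.46 ± 0.02 with an adjusted p of 9.7e-18, and MSTRG.21116 from 352 ± 11.9 to 1955 ± 36.6 FPKM. Photosystem and electron transport genes rose in 26 of 43 cases and fell in 2, and Calvin cycle genes in 9 of 11 and 0, with 28 and 9 passing when adjusted over the list alone (medians 0.68 and 1.24). Their adjusted p were 0.00011 and 0.00042 (adjusted p = 0.22 and 0.17 with an estimated correlation). Photosystem I subunit K (MSTRG.22413) rose from 145 ± 4.91 to 818 ± 17.5 FPKM, Rubisco activase 2 (MSTRG.22136) from 588 ± 10.3 to 2097 ± 25.5 FPKM. Rubisco activase 1 (MSTRG.9620) rose from 154 ± 4.75 to 1653 ± 1.66 FPKM, above its level in every other group. Ribosomal proteins fell in 126 of 226 cases and rose in 32, with 163 passing when adjusted over the list alone (median -0.39, adjusted p = 7.4e-06; adjusted p = 0.22 with an estimated correlation). S6 (MSTRG.10579) fell from 426 ± 14.7 to 218 ± 3.01 FPKM.

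DnaJ co-chaperones fell in 27 of 60 cases and rose in 15, with 44 passing when adjusted over the list alone (median -0.29, adjusted p = 0.037; adjusted p = 0.18 with an estimated correlation). A chloroplast DnaJ 8 gene (MSTRG.21353) fell from 353 ± 22.6 to 75.8 ± 2.97 FPKM, and a B-type DnaJ gene (MSTRG.19199) rose from 11.5 ± 0.838 to 73.0 ± 1.81 FPKM. The small heat shock protein list did not pass, with 10 of 32 higher, 13 lower and a median of 0.01 (adjusted p = 0.71). Single members went both ways: MSTRG.22177 fell from 4317 ± 79.7 to 3463 ± 62.4 FPKM, while MSTRG.5787 rose from 1928 ± 43.0 to 3464 ± 24.3 FPKM (adjusted p = 3.7e-05). The wax and fatty acid, flavonoid, auxin and jasmonate lists that were lower at 40 °C than at 25 °C did not pass for melatonin either, with medians of 0.04, 0.30, 0.06 and 0.35 and adjusted p of 0.97, 0.29, 0.79 and 0.20. The test compares a list with the other genes, so this does not show that their members failed to rise.

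Granule-bound starch synthase (MSTRG.5792) had the largest rise among the named genes with melatonin at 40 °C that are single-gene loci, from 3.95 ± 0.278 to 341 ± 4.86 FPKM (log2 fold change 6.24 ± 0.05, adjusted p = 1.3e-18). The light-harvesting gene MSTRG.24636 rose from 3.24 ± 0.377 to 111 ± 1.75 FPKM, the aquaporin MSTRG.8662 from 0.644 ± 0.0690 to 31.0 ± 2.88 FPKM and an enzyme of methionine salvage, 1,2-dihydroxy-3-keto-5-methylthiopentene dioxygenase (MSTRG.7797), from 32.3 ± 3.91 to 603 ± 4.09 FPKM. Falls included the xyloglucan endotransglucosylase/hydrolase MSTRG.22297, from 599 ± 13.4 to 0.280 ± 0.243 FPKM, and the germin-like MSTRG.23584, from 299 ± 26.4 to 0.132 ± 0.229 FPKM. A pectate lyase (MSTRG.14880), which cleaves pectin, fell from 318 ± 7.28 to 2.63 ± 0.843 FPKM, and the NIP-type aquaporin-like MSTRG.17531, from 85.2 ± 6.11 to 0.0781 ± 0.135 FPKM. The list of 140 genes for cell wall loosening and remodelling did not pass, with 32 higher and 40 lower (adjusted p = 0.53). Among heat stress transcription factors HSF B3 (MSTRG.4397) fell from 121 ± 1.47 to 37.9 ± 2.36 FPKM, and an A-8-like factor (Rhsim09G0088300) rose from 1.13 ± 0.294 to 4.92 ± 0.328 FPKM. The melatonin biosynthesis list matched 1 tested gene, a merged locus described as a reticuline O-methyltransferase (MSTRG.24247). Its level fell from 0.960 ± 0.0458 at 25 °C to 0.313 ± 0.0758 at 40 °C and rose to 4.12 ± 0.969 FPKM with melatonin (adjusted p = 0.00012 and 5.3e-08).

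Melatonin at 40 °C changed 15466 genes, 8605 higher and 6861 lower, of which 4247 and 2894 changed at least 2-fold. The share of rises moved with the scaling: on FPKM as deposited limma called 10423 higher and 5227 lower, with a median log2 fold change of 0.23 against 0.10 in the count test. On rescaled FPKM it called 7594 higher and 7391 lower, 2074 and 2302 of them at least 2-fold. The mitochondrial share of counts was 0.0619% ± 0.0064 with melatonin against 0.214% ± 0.011 without.

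**Figure D3:**
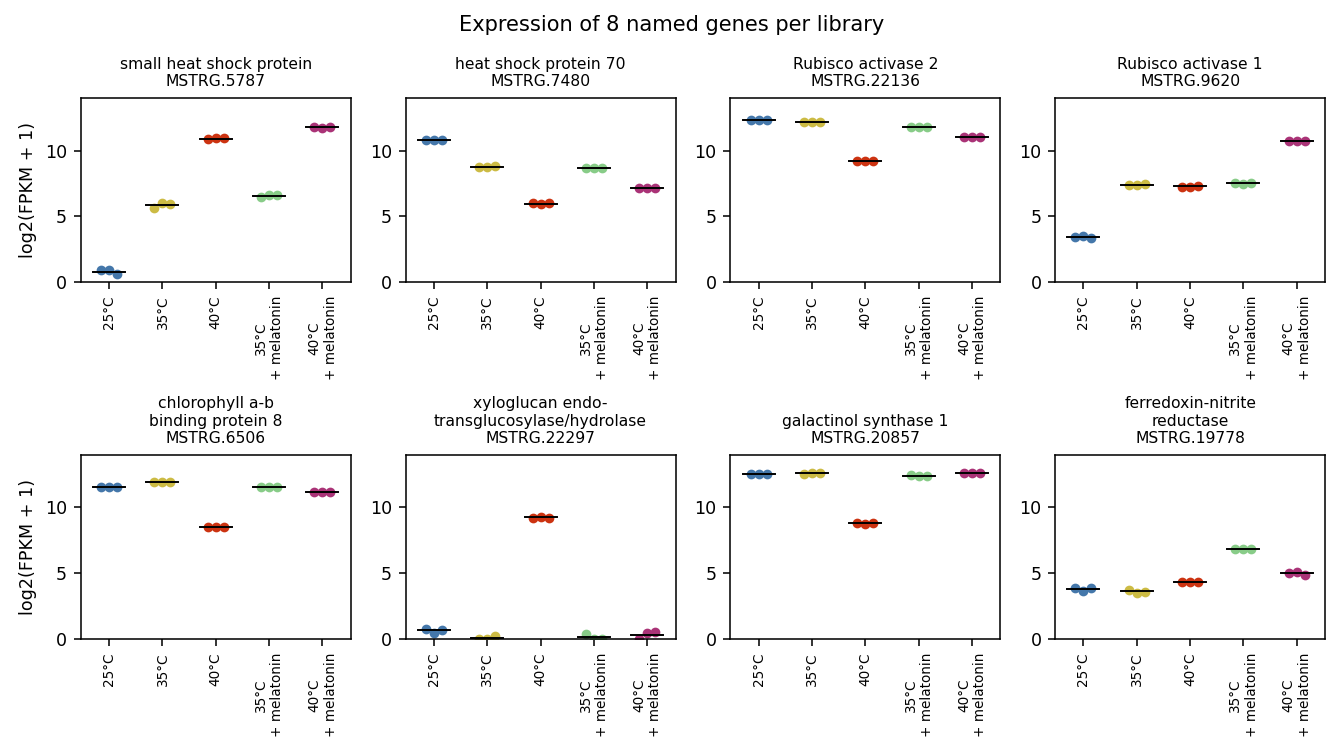
Expression of 8 named genes in each of the 15 libraries (points, log2(FPKM + 1), 3 libraries per group, horizontal line at the group mean). Rubisco activase 2, chlorophyll a-b binding protein 8 and galactinol synthase 1 are lowest at 40 °C without melatonin, the xyloglucan endotransglucosylase/hydrolase is high in that group alone (599 FPKM), and nitrite reductase peaks at 35 °C with melatonin (115 FPKM).

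Whether melatonin acted differently at the 2 temperatures was tested by the difference of its effects. With melatonin at 35 °C, 20 of 43 photosystem and electron transport genes, 8 of 17 light-harvesting genes and 7 of 11 Calvin cycle genes fell, and at 40 °C 26, 13 and 9 of them rose. The light-harvesting call at 35 °C (adjusted p = 0.096 with an estimated correlation) and all 3 at 40 °C (adjusted p = 0.22, 0.17 and 0.17 with an estimated correlation) were lost when the correlation was estimated. The median difference in log2 fold change, 40 °C minus 35 °C, was 1.68 for light-harvesting proteins (12 of 17 higher, 1 lower), 0.82 for photosystems and electron transport (28 of 43 higher, 1 lower) and 1.55 for the Calvin cycle (10 of 11 higher, 0 lower). Of these lists, 14, 30 and 10 genes passed when adjusted over the list alone. Their adjusted p were 3.8e-05, 8.7e-08 and 7.8e-06 (adjusted p = 0.082 for each with an estimated correlation). Galactinol synthase 1 (MSTRG.20857, chromosome 12, 18674010 to 18677112), which makes the galactosyl donor for raffinose-type sugars, had the smallest adjusted p, 4.3e-18. It stood at 6215 ± 165 FPKM at 35 °C and 5419 ± 112 with melatonin, and at 441 ± 7.44 at 40 °C and 6125 ± 33.1 with melatonin. A UV-B receptor-like gene (MSTRG.17436) went from 175 ± 4.35 to 142 ± 3.18 FPKM with melatonin at 35 °C and from 1456 ± 26.4 to 141 ± 2.53 at 40 °C. A fatty acid hydroperoxide lyase (MSTRG.6746), which makes leaf aldehydes, went from 143 ± 2.62 to 119 ± 5.01 and from 6.29 ± 0.254 to 84.3 ± 0.901 FPKM in the same order. In all, the melatonin effect differed between temperatures for 12694 genes, 7125 with a larger log2 fold change at 40 °C and 5569 with a smaller one. Of these, 3595 and 2739 differed at least 2-fold, against 2008 and 2580 by limma on rescaled FPKM.

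The last comparison asked whether genes moved by heat moved back with melatonin. Of the 6397 genes at least 2-fold higher at 40 °C than at 25 °C, 3472 (54.3%) were lower with melatonin and 599 higher still, against 1676 and 2102 for independent lists. Of the 6776 genes at least 2-fold lower, 4532 (66.9%) were higher with melatonin and 291 lower still, against 2227 and 1776. At 35 °C, 380 of 2283 heat-raised genes (16.6%) were lower with melatonin and 165 higher still, against 281 and 221, and 672 of 2090 heat-lowered genes (32.2%) were higher and 101 lower still, against 203 and 257. The counts for independent lists leave out that the untreated heat libraries enter both fold changes, which by itself favours opposite moves. Among genes at least 2-fold apart in mean log2 CPM with heat, called or not, 68.6% of 6242 moved the opposite way with melatonin at 35 °C and 59.4 to 61.6% when different heat libraries entered the 2 fold changes. At 40 °C these shares were 79.3% of 14516 genes and 76.3 to 77.2%. The median share of the heat shift left with melatonin was 0.82 at 35 °C and 0.61 at 40 °C. Across genes, the covariance of the heat and melatonin log2 fold changes was -2.48 at 40 °C (r = -0.67) and -0.28 at 35 °C (r = -0.33). The untreated heat libraries enter both fold changes with opposite signs, and simulated groups without any effect gave a covariance of -0.11 (-0.12 to -0.10) and an r of -0.50 at either temperature. The simulated groups lack the heat effect as well, so their r is not comparable with the observed ones, and only the covariances are compared. The difference from the simulated covariance was -2.37 at 40 °C and -0.17 at 35 °C. With different heat libraries in the 2 fold changes, the covariance was -2.38 to -2.33 at 40 °C and -0.18 to -0.15 at 35 °C. Genes are not independent replicates, so no p-value is given.

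**Figure D4:**
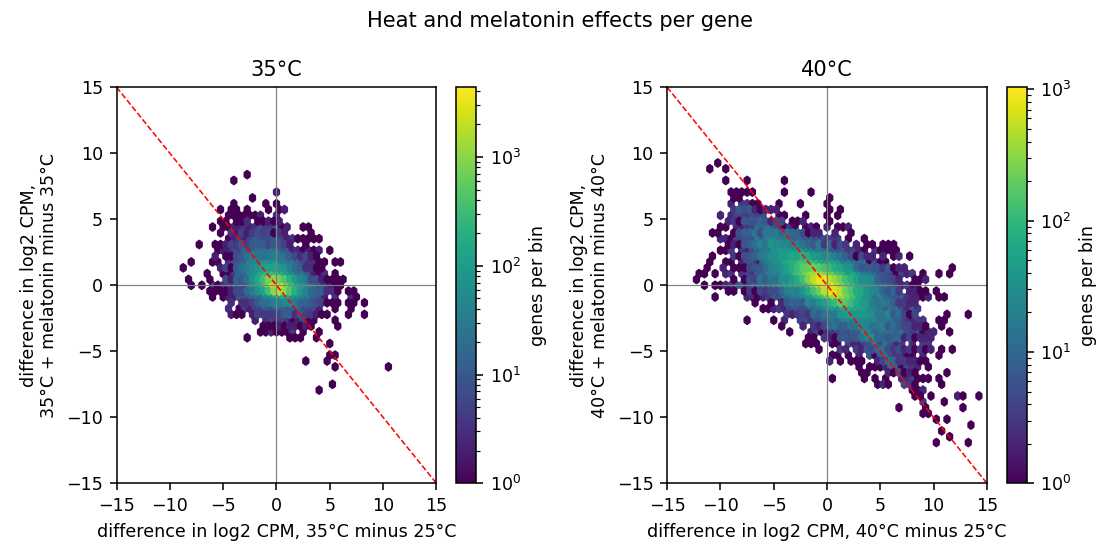
Difference in mean log2 CPM with melatonin (vertical axis) against the difference with heat (horizontal axis, 35 °C or 40 °C minus 25 °C) for the 26183 tested genes, binned by hexagon with colour giving genes per bin on a log scale and a dashed line marking a full return to the 25 °C level. The cloud is tilted towards that line at 40 °C (covariance of the 2 plotted differences -2.48) and much less at 35 °C (-0.28).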

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

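Of the tests below, those on shared libraries and on a mixture of RNA were chosen only after the result was seen, while the regroupings of libraries were set in advance.

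The effect of melatonin differed between 35 °C and 40 °C for 12694 genes. The photosynthesis lists rose with melatonin at 40 °C relative to 35 °C, with median differences in log2 fold change of 1.68 for light-harvesting proteins, 0.82 for photosystems and electron transport and 1.55 for the Calvin cycle (adjusted p = 0.082 for each with an estimated correlation). Single genes with the smallest adjusted p were galactinol synthase 1 (MSTRG.20857, difference 3.91), granule-bound starch synthase (MSTRG.5792, 6.80), light-harvesting protein 8 (MSTRG.6506, 2.94), Rubisco activase 2 (MSTRG.22136, 2.12), a UV-B receptor-like gene (MSTRG.17436, -3.16) and a fatty acid hydroperoxide lyase (MSTRG.6746, 3.92). Each of the 6 was moved further by melatonin at 40 °C than at 35 °C. Of 100 regroupings drawn from 200, 2 gave at least as many genes, the real one included. The other gave 13360 and swaps the melatonin labels of 1 temperature as a whole, so that it tests the sum of the melatonin effects instead of their difference. Another 13 kept the 40 °C labels whole and mixed those at 35 °C, and they gave 10447 to 10966 genes, so much of the count arises from the melatonin effect at 40 °C whatever the grouping at 35 °C. With only the 35 °C labels whole, 10 gave 135 to 205 genes, and 75 with labels mixed at both temperatures gave at most 1. Random assignment of libraries at both temperatures is excluded as the source of this count. Mixing libraries of unlike groups widens the spread, so few calls there would follow from any melatonin effect. The mixed regroupings therefore do not bear on whether that effect differs between temperatures.

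For each pairwise comparison only 10 regroupings of 3 and 3 libraries exist, too few for a share under 0.05. The real grouping was the 1 with most genes in each: 12846 against at most 1 for 35 °C and 25 °C, 19861 against 1 for 40 °C and 25 °C, 18154 against 1 for 40 °C and 35 °C, 5763 against 3 for melatonin at 35 °C and 15466 against 5 for melatonin at 40 °C. Here too, mixing libraries of unlike groups widens the spread, so few calls would follow from any difference between the groups. The size of these gaps therefore adds no support.

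With melatonin at 40 °C, genes moved back towards their level at 25 °C. Examples are Rubisco activase 2, granule-bound starch synthase and the cell wall enzyme MSTRG.22297. The return was partial: among genes at least 2-fold apart with heat, a median share of 0.61 of the shift was left. Between 40 °C with melatonin and 25 °C, 17692 genes were still called, 9769 of them at least 2-fold. Noise of single 40 °C libraries shared by both fold changes does not explain the move back. With different 40 °C libraries the covariance was at most -2.33, against a lower simulated bound of -0.12 for no effect. A deviation common to all 3 libraries at 40 °C would still enter both fold changes, and this was not tested. A mixture of RNA from the other groups would leave genes between their levels, but 2.45% of genes (344 above and 298 below) lay at least 2-fold outside the range of the other 4 groups. A mixture of these 4 groups alone is therefore excluded, while a mixture with RNA from any other source was not tested. An effect of melatonin on heat tolerance and a milder heat exposure of the melatonin plants would both move genes in this way, and neither was tested. No sample in the labels is at 25 °C with melatonin, and the table columns whose names carry MT and 25 were not analysed here, so an effect of melatonin apart from heat was not tested either.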

How the results depend on the processing

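No named gene reversed direction under any alternative run for it, and no called gene list did under the 4 run for lists (estimated correlation, fry, median-of-ratios scaling and a replicate block). The balance of higher and lower genes did: in each of the 6 comparisons the larger direction changed under at least 1 alternative. With median-of-ratios scaling it was 6219 higher and 6598 lower for 35 °C with 25 °C, 9946 and 9943 for 40 °C with 25 °C, and 9120 and 9079 for 40 °C with 35 °C. On FPKM as deposited it was 4330 and 2114 for melatonin at 35 °C. A fit on the compared groups alone gave 7294 and 7569 for melatonin at 40 °C, and rescaled FPKM 6260 and 6674 for the difference of the melatonin effects. The cause was not tested. The counts of genes in the order 35 °C and 40 °C with 25 °C, 40 °C with 35 °C, melatonin at 35 °C, melatonin at 40 °C and their difference were 11589 to 11995, 19137 to 19340, 17429 to 17633, 4608 to 4948, 14320 to 14568 and 11851 to 12289 when 1 library was left out. Over the other alternatives at the same threshold they were 11109 to 13708, 14532 to 20456, 13903 to 18963, 5419 to 6656, 12772 to 16922 and 11022 to 14098. Asking for at least 2-fold changes left 4373, 13173, 10602, 1204, 7141 and 6334 genes, and an adjusted p under 0.01 left 3704 for melatonin at 35 °C; these thresholds are stricter by construction. The covariance at 40 °C was -2.57 to -2.47 with 1 library left out and -3.15 to -0.92 otherwise, and at 35 °C -0.37 to -0.27 and -0.37 to -0.085. The value of -0.085 is from rescaled FPKM, where simulated groups without effects gave -0.017 (-0.020 to -0.015). With an estimated correlation the number of lists fell to 0 for 35 °C with 25 °C, 2 for 40 °C with 25 °C, 0 for 40 °C with 35 °C, 0 for melatonin at 40 °C and 0 for the difference, and 18 of 55 calls were kept; the cause was not tested. The fry test called 37, 42, 41, 36, 35 and 39 lists, since it does not compare a list with other genes. With median-of-ratios scaling 54 of the 55 list calls were kept. Fold changes of MSTRG.5298, MSTRG.23584 and MSTRG.17531 depend on near-zero counts, so their levels alone are given.

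With a replicate block, treating libraries of the same number as paired, 12471, 19589, 17865, 5455, 15063 and 12334 genes were called. Residuals of the 30 same-number pairs correlated at -0.056 to 0.029, so the numbers do not pair the libraries.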

Other observations

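Among the tests below, those of KEGG pathways, of genes outside the range of other groups, of the few mitochondrial genes with most counts and of scaling were chosen only after the result was seen.

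Pathway annotation adds to the gene lists. At 40 °C against 25 °C, anthocyanin biosynthesis genes fell in 20 of 22 cases (median log2 fold change -5.49, adjusted p = 0.0079; adjusted p = 0.11 with an estimated correlation). Stilbenoid, diarylheptanoid and gingerol genes fell in 32 of 46 (median -3.21, adjusted p = 0.029; adjusted p = 0.11 with an estimated correlation). Of the 22 anthocyanin biosynthesis genes, 11 were higher with melatonin at 40 °C than without and 1 was lower (median 1.99). The pathway did not pass the camera test for that comparison (adjusted p = 0.21). At 35 °C against 25 °C, carbon fixation genes fell in 39 of 69 cases (adjusted p = 0.00021) and oxidative phosphorylation genes in 62 of 154 (adjusted p = 0.018), and both held with an estimated correlation. Proteasome genes fell there in 55 of 86 cases and held too (adjusted p = 0.013 with an estimated correlation), unlike the narrower list of subunits. For the difference of melatonin effects, antenna protein genes were higher in 11 of 12 cases (median 2.11) and held (adjusted p = 0.042 with an estimated correlation), where the list of light-harvesting proteins did not. Galactose metabolism held as well and went the other way, lower in 43 of 116 cases and higher in 26 (median -0.38, adjusted p = 0.023; adjusted p = 0.042 with an estimated correlation). With melatonin at 35 °C, phenylpropanoid genes rose in 45 of 191 cases (adjusted p = 0.00052), 31 of them at least 2-fold, and held as well. Ribosome and photosynthesis pathway genes fell there in the camera test with the preset correlation (adjusted p = 2.0e-11 and 9.8e-07). They did not hold (adjusted p = 0.082 and 0.13 with an estimated correlation), unlike the lists of ribosomal proteins and of photosystems and electron transport.

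Some genes at 40 °C with melatonin lay outside all other groups. An abscisic acid receptor-like gene (MSTRG.9907) was at 106 ± 2.73 FPKM there against 10.7 ± 2.34 at 40 °C and 19.0 ± 2.15 at 25 °C (mean ± SD, n = 3). A glyceraldehyde-3-phosphate dehydrogenase (MSTRG.20220), an enzyme of glycolysis, was at 244 ± 4.45 FPKM against 57.5 ± 3.18 at 40 °C, and a mitoferrin-like iron carrier (MSTRG.9923) at 325 ± 12.8 against 65.0 ± 2.38. Below all others were expansin-A1 (MSTRG.20456), which loosens cell walls, at 5.27 ± 0.713 FPKM against 247 ± 6.02 at 40 °C, and a pectinesterase (MSTRG.2849) at 12.4 ± 0.844 against 93.0 ± 1.05. These genes were chosen after their values were seen.

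Transcripts of the mitochondrial genome were higher at 40 °C, where 32 of 42 tested genes rose at least 2-fold and 4 fell (median log2 fold change 3.10), and with melatonin at 40 °C 30 of the 42 fell at least 2-fold (median -2.17). Genomic DNA or a failed polyA selection would raise plastid transcripts too, were these otherwise unchanged. Their median at 40 °C was -1.82 over 19 genes, with 0 called higher and 16 lower, so no such rise was seen across them. The plastid locus with the highest FPKM, MSTRG.67, was at 641 FPKM at 40 °C against 438 at 25 °C, a difference that was not called (edgeR adjusted p = 0.085). It was lower with melatonin at 40 °C (log2 fold change -1.34, adjusted p = 0.0025). Nuclear photosynthesis transcripts also fell at 40 °C, and a true fall of plastid transcripts could hide a small carry-over. This comparison therefore cannot exclude one. The rise was not confined to a few of the loci listed, since 32 of the 42 rose. Some of these loci overlap or share a description, such as MSTRG.11 and MSTRG.49, both ATPase subunit 1. Many were under 1 FPKM at 25 °C, so the 42 are not separate, well-measured genes. Most of the rise in the share of counts lay in the 3 loci with most counts at 40 °C, which were picked by those counts. Without them the share went from 0.0081% at 25 °C to 0.0305% at 40 °C, against 0.0239% to 0.214% with all. The remaining loci rose as well, to 3.77 times their share at 25 °C (3.16 to 4.71 over pairs of libraries), against 8.97 with all. The ratio of 3.77 lies between the bounds of 2 and 4 set for it, and not every pair of libraries was over 4. By those bounds the test did not decide. A loss of nuclear mRNA at 40 °C, or more polyadenylated mitochondrial RNA, was not tested.

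Changes of at least 2-fold with melatonin at 35 °C were mostly rises, nitrite reductase and WRKY31 among them. The scaling between libraries is excluded as the source, since the lowest share of rises over the scalings was 83.5%. Among genes with a mean FPKM of at least 5 over all 15 libraries the share was 81.3% (309 rises and 71 falls). That mean includes the raised group, so genes near the detection limit at 35 °C without melatonin can pass. The phylloplanin-like MSTRG.2278, at 0.907 to 1.20 FPKM there, is such a gene. A low starting level is therefore not excluded as a source of the rises. Activation of defence and phenylpropanoid genes by melatonin, or by how it was applied, was not tested. The list of 265 defence and pathogenesis-related genes was not among the lists called for this comparison.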
